A study of Arabidopsis thaliana with 12 samples.

How the data were processed

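Whole Arabidopsis thaliana seedlings of the wild type Col-0 and of the mutant bhlh93-1, which affects the basic helix-loop-helix transcription factor bHLH93, were profiled on 12 single-colour arrays. Per the labels, seeds were stratified for 4 days and grown on medium without sucrose in short days of 8 h light and 16 h dark. The seedlings were 10 days old when harvested, either in the dark (0 h) or 4 h after the light came on. From 5 µg of total RNA, double-stranded cDNA was made with an oligo-dT primer and labelled with Cy3 through random nonamers and Klenow enzyme, then hybridised to NimbleGen arrays. By the array names Col-0 arrays hold positions 1 to 6 and bhlh93-1 arrays 7 to 12, with 0 h and 4 h alternating.

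The authors deposited one file per array with expression values on a log2 scale, summarised by RMA per transcript model; the version of their software and the background setting are not given in the sources used here. Each array holds 37118 transcript models, of which 71.1% rest on 4 probes and 28.5% on 3. The deposited series table gives the same values as linear intensity: its log2 differed from the array files by at most 7.2e-10, with 1 empty cell, so it carries no separate information. The log2 values run from 5.4472 to 15.4657. No background or detection value per gene comes with the files analysed here, so the number of arrays sets the precision. The median standard error of a genotype difference at one time was 0.244 on the log2 scale.

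The models belong to 32627 loci. Where a locus had several models (3602 loci), the one with the highest mean over all 12 arrays was kept, and no filter on dim genes was applied. Gene symbols came from the RefSeq gene table of assembly TAIR10.1, used only for names and for which genes neighbour each other. It matched 31993 loci and gave a symbol for 10597. The build behind the probes is not given in the sources used here, so no coordinates are printed.

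Differences were fitted with limma 3.58.1 in R 4.3.3, as a model of 4 group means over all 12 arrays with empirical Bayes moderation (8 residual and 9.64 prior degrees of freedom). All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all loci, with a gene called at an adjusted p under 0.05. The 6 contrasts were the genotype difference at 0 h, at 4 h and averaged over both times, the change from 0 h to 4 h in each genotype, and the interaction of genotype and time. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples. They do not say what a replicate number marks either. After each group's mean was removed, 4 of 18 pairs of arrays with the same number correlated above 0.1 across genes (r from -0.244 to 0.192), and 13 of 36 best matches fell on the same number. The arrays were therefore treated as unpaired, and a replicate block was fitted only as an alternative. On simulated data with the same spread, the fit recovered 35 of 100 genes given a log2 change of 1 and 89 of 100 given a change of 2, with 2 false calls.

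The contrasts, the test, the gene lists, the rule for named genes and nearly all alternatives were fixed before the data were examined. The 29 lists hold 432 entries, of which 431 were on the arrays (BZIP1 was not). They cover gibberellin (GA) synthesis, inactivation and response, flowering, the clock, light, photosynthesis, sugar and nitrate status, hormones, stress, the cell cycle, and markers of root, shoot meristem, stomata and seed. RVE3 (ASG4 in the reference table) was kept in the morning clock list. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01 and, as an alternative, with the correlation estimated per list, adjusting over the lists within a contrast. Members called are counted over all loci tested and adjusted over the list alone. On simulated data a list shifted by 0.5 was called and 0 of the 28 others were. Simulated genes were independent, so the preset correlation stays untested.

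Genes are named by a fixed rule. Per contrast it takes the 10 largest rises and 10 largest falls among called genes with a symbol whose groups do not overlap (at each time, for the averaged contrast), and up to 2 called members per list in each direction. Where a list has none called, at most 2 members with the smallest p are given as values. bHLH93, its neighbours within 3 loci on either side and 14 genes of flowering, GA and the clock are always included. With no gene called in the interaction, the 5 smallest p-values are given there.

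The alternatives were cyclic loess across the arrays, dropping the dimmest 25% of genes, a trended and robust variance, a replicate block, array position as a linear covariate, the series table's values, the mean of a locus's models, a fit on the arrays of the contrast alone, and leaving out each array in turn. The gene lists were also recomputed without each array in turn, a choice made after seeing the data. Other splits of the arrays were counted for each number of called genes, all 10 where 3 arrays face 3 and 100 drawn with a fixed seed otherwise.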

Results

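Transcript levels were measured in whole 10-day-old seedlings grown in short days, in 4 groups of 3 arrays: Col-0 and bhlh93-1, each in the dark (0 h) and 4 h after the light came on. The study asks how the transcription factor bHLH93 controls flowering time. All values are log2 RMA expression, and differences are given with the standard error from limma (n = 3 arrays per group unless stated). The log2 values were spread less widely on bhlh93-1 arrays, with an SD per array of 1.565 ± 0.053 (SD, n = 6) against 1.708 ± 0.037 (SD, n = 6) in Col-0 (exact permutation test, two-sided, p = 0.00216, the smallest it can give). Dim genes read higher and bright genes lower in the mutant. At 0 h the median difference ran from 0.31 in the dimmest 10% of genes to -0.33 in the brightest 10%, and after cyclic loess these were 0.01 and 0.01. The array bhlh93-1 0 h replicate 2 resembled its group least, with a mean correlation across genes of 0.909. A difference between positions 1 to 6 (Col-0) and 7 to 12 (bhlh93-1) cannot be told from a genotype difference.

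For bHLH93 itself (AT5G65640) limma called no difference between the genotypes. The locus has 2 transcript models of 3 probes each. The log2 difference of the model kept, averaged over both times, was 0.05 ± 0.21 (SE, n = 6 per genotype; adjusted p = 0.863), and -0.12 after cyclic loess. The other model lay lower in bhlh93-1 at both times, by less than the larger SD of each pair: 7.68 ± 0.14 (SD, n = 3) against 7.89 ± 0.35 at 0 h, and 7.82 ± 0.59 against 7.95 ± 0.05 at 4 h. Where the probes lie relative to the mutation is not given in the sources used here, so these values do not test the mutant. Of its measured neighbours, AT5G65650 rose by 0.54 ± 0.14 (adjusted p = 0.00943) and AT5G65620 and GTE7 fell by 0.64 ± 0.17 and 0.55 ± 0.17. With array position as a covariate these calls ended (adjusted p = 0.283, 0.166 and 0.315), and that of GTE7 also without Col-0 0 h replicate 3, Col-0 4 h replicate 2 or bhlh93-1 4 h replicate 2 (0.0605, 0.0566 and 0.0635) and after cyclic loess (0.112). AT5G65660 differed by -0.001 (adjusted p = 0.996), a value that turned to 0.41 after cyclic loess.

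At 0 h, the end of the night, the comparison asks what the mutation changes before dawn. The lists of light-harvesting, chlorophyll synthesis, dark- or low-sugar-induced and morning clock genes lay lower in bhlh93-1 at the preset correlation of camera, and each lost its call with an estimated correlation (adjusted p = 0.468) and after cyclic loess (0.0607 to 0.533). LHCB1.3 (AT1G29930), a light-harvesting chlorophyll-binding protein, fell 3.54-fold (log2 -1.82 ± 0.25, adjusted p = 0.00167), and HEMA1 (AT1G58290), which starts tetrapyrrole synthesis, fell 2.58-fold (log2 -1.37 ± 0.25). ELF3 (AT2G25930), a component of the evening complex of the clock, fell 3.05-fold (log2 -1.61 ± 0.25), and ELA2 (AT5G24900), a cytochrome P450 that inactivates GA, rose 2.67-fold (log2 1.42 ± 0.30). In all, 22% of the loci were called: 3751 genes were higher and 3433 lower in bhlh93-1, of which 1466 and 1442 differed by 2-fold or more. Which direction held more genes turned with the setting: 2715 were higher and 3013 lower after cyclic loess, and 2831 and 3561 with dim genes dropped. It turned as well without Col-0 0 h replicate 3 (819 and 993) or bhlh93-1 0 h replicate 2 (1430 and 1568) and when only the arrays of these groups were fitted (1345 and 1420). The rise of ELA2 was 4.26-fold with array position as a covariate.

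The largest rises at 0 h were in LBD28 (AT3G50510), a LOB-domain protein (4.08-fold, log2 2.03 ± 0.33, adjusted p = 0.0026), LCR1 (3.39-fold, adjusted p = 0.0497, and 1.45-fold without bhlh93-1 0 h replicate 2), LCR13 (3.36-fold), bZIP42 (3.34-fold), GATA14 (3.31-fold), LBD40 (3.31-fold), FUT5, AGP6, MBD12 and MAF5. MAF5 (AT5G65080), a relative of the floral repressor FLC, rose by 1.72 ± 0.30. The largest falls were in U1.5 (6.87-fold, log2 -2.78 ± 0.41, adjusted p = 0.00188), the RNA-binding YTH protein gene ECT3 (4.49-fold), the chloroplast ferric reductase gene FRO7 (4.22-fold), the fatty acid elongase gene KCS16 (4.05-fold), MET18 (4.05-fold), RPP5, GRXS13, RPL5B, EXO70G1 and MEF8S. For each of these 20 genes all 3 bhlh93-1 arrays lay on one side of all 3 Col-0 arrays. The call of LCR1 ended without Col-0 0 h replicate 1, 2 or 3 (adjusted p = 0.0627, 0.116 and 0.137) or bhlh93-1 0 h replicate 2 (0.121), with a range of 0.013 to 0.312 over the alternatives; its rise was 5.17-fold and 5.21-fold without bhlh93-1 0 h replicates 1 and 3. The call of LBD40 ended without Col-0 0 h replicate 3 (0.0702) or bhlh93-1 0 h replicate 2 (0.0586), and without Col-0 0 h replicate 1 its rise was 4.98-fold. Without bhlh93-1 0 h replicate 2 the log2 falls of RPL5B and EXO70G1 went from -1.90 to -1.17 and from -1.88 to -1.05, and without replicate 3 that of EXO70G1 was -2.54. The calls of LCR13, FUT5, MAF5, MET18, RPL5B and EXO70G1 ended with array position as a covariate (0.0535 to 0.156), and that of GRXS13 when the models of a locus were averaged (0.0842), where its fall was 1.44-fold. The rise of MAF5 was 0.76 there. U1.5 fell 16.8-fold and ECT3 9.42-fold with array position as a covariate, and MBD12, bZIP42 and LBD40 rose 6.34-fold, 5.78-fold and 5.66-fold.

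Among the lists at 0 h, 11 of 23 dark- or low-sugar-induced genes fell, and 11 adjusted over the list alone (camera adjusted p = 4.45e-06, and adjusted p = 0.468 with an estimated correlation); TPS8, a trehalose phosphate synthase relative, fell by 1.33 ± 0.28 and the proline dehydrogenase gene PRODH1 by 1.24 ± 0.26. Of 15 chlorophyll synthesis genes 8 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.000188, and adjusted p = 0.468 with an estimated correlation). Those that fell include HEMA1 and GSA1 (log2 -1.76 ± 0.39), and the one that rose is PORA, a protochlorophyllide reductase. Of 20 light-harvesting genes 7 fell (9 adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.468 with an estimated correlation), among them LHCB1.2 (log2 -1.23 ± 0.24, and -0.80 after cyclic loess). Of 20 morning clock genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.000229, and adjusted p = 0.468 with an estimated correlation). LNK2 fell 2.64-fold, RVE4 and CCA1 fell by 1.45 ± 0.32 and 0.88 ± 0.24, and PRR9 rose by 0.92 ± 0.24. Of 12 autonomous and vernalization pathway genes 3 fell (5 adjusted over the list alone, camera adjusted p = 0.00854, and adjusted p = 0.468 with an estimated correlation), among them VEL1 (log2 -0.86 ± 0.21). Of 11 GA inactivation genes 3 rose (6 adjusted over the list alone, camera adjusted p = 0.0301, and adjusted p = 0.468 with an estimated correlation); these include ELA2 and the GA 2-oxidase gene GA2OX3 (log2 1.07 ± 0.37). Of 11 seed storage and late embryo markers 4 rose (4 adjusted over the list alone, camera adjusted p = 0.0409, and adjusted p = 0.468 with an estimated correlation), among them the storage protein gene CRB (log2 0.93 ± 0.23). All 7 list calls were lost after cyclic loess, with adjusted p from 0.0607 to 0.533 and a median of -0.03 for light harvesting. With dim genes dropped the autonomous pathway had 0.0588. With array position as a covariate the calls of light harvesting (0.274), the autonomous pathway (0.0747), GA inactivation (0.0747) and seed storage (0.199) were lost. Without Col-0 0 h replicate 3 the GA inactivation call ended (0.0593), and the seed storage call ended without Col-0 0 h replicate 1 (0.0931) or bhlh93-1 0 h replicate 2 (0.103). The counts moved with single arrays. With Col-0 0 h replicate 3 left out, the genes that fell were 2 dark- or low-sugar-induced, 4 chlorophyll synthesis, 4 light-harvesting, 4 morning clock and 1 autonomous pathway genes, and 1 GA inactivation gene rose. With bhlh93-1 0 h replicate 2 left out they were 3 dark- or low-sugar-induced, 5 chlorophyll synthesis and 4 morning clock genes, and 1 GA inactivation gene and 2 seed storage markers rose. With Col-0 0 h replicate 2 left out they were 3 dark- or low-sugar-induced, 5 chlorophyll synthesis and 1 autonomous pathway genes, and 2 seed storage markers rose. With bhlh93-1 0 h replicate 1 left out 7 dark- or low-sugar-induced genes fell, and 6 and 5 GA inactivation genes rose without Col-0 0 h replicate 1 and bhlh93-1 0 h replicate 3. The calls of CCA1, PRR9, PORA and GA2OX3 ended without Col-0 0 h replicate 3 (adjusted p = 0.0735, 0.0869, 0.21 and 0.253). Those of CCA1, PORA and GA2OX3 ended without bhlh93-1 0 h replicate 2 (0.0761, 0.224 and 0.226). That of PORA ended without Col-0 0 h replicate 2 (0.0727) and that of PRR9 without bhlh93-1 0 h replicate 1 (0.0501). The rise of GA2OX3 was 0.61 without Col-0 0 h replicate 3 and 0.64 without bhlh93-1 0 h replicate 2, and without the latter array PORA rose by 0.42 and GSA1 differed by -1.13. The calls of PRODH1, GSA1, RVE4, VEL1 and CRB ended with array position as a covariate (0.052 to 0.14), which took PRR9 to 1.49. After cyclic loess CCA1, PORA and GA2OX3 had 0.0963, 0.0576 and 0.0914.

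The other 22 lists were not called at 0 h, with camera adjusted p from 0.0616 to 0.996. Of 20 floral integrators and promoters 3 rose (3 adjusted over the list alone, camera adjusted p = 0.0676), among them the MADS-box genes AGL24 (log2 1.04 ± 0.27) and AP1 (log2 1.03 ± 0.29). Of 18 phenylpropanoid and flavonoid genes 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.252). The flavonol regulator MYB12 rose by 1.03 ± 0.24. Of 19 salicylic acid and defence genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0975). The touch genes TCH4 and TCH3 fell by 1.57 ± 0.33 and 1.56 ± 0.30, 2 of the 9 members of their list (2 adjusted over the list alone, camera adjusted p = 0.102). In light signalling the SPA repressors SPA3 and SPA1 fell by 1.17 ± 0.23 and 1.16 ± 0.25 (1 rose and 3 fell of 16, the same adjusted over the list alone, camera adjusted p = 0.0978). In the evening clock list 3 of 11 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.615). ELF4 rose by 0.88 ± 0.20. The calls of AGL24 and AP1 ended without bhlh93-1 0 h replicate 2 (adjusted p = 0.0669 and 0.0998, with AP1 at 0.68) and those of AP1 and MYB12 without Col-0 0 h replicate 3 (0.112 and 0.052). Of these genes TCH3 kept its call with array position as a covariate (0.0498), and the others had 0.052 to 0.372, with AGL24 at 0.65. The counts of these lists moved with single arrays. Leaving out bhlh93-1 0 h replicate 2 left 0 floral integrators, 2 phenylpropanoid and flavonoid genes, 2 defence genes and 0 light signalling genes that rose, and 0 flavonoid and 0 defence genes that fell. Leaving out Col-0 0 h replicate 3 left 1 rise each among the floral integrators, flavonoid, defence and evening clock genes and 0 in light signalling, with 0 flavonoid and 0 defence genes that fell. Leaving out Col-0 0 h replicate 2 left 4 flavonoid genes that rose and 0 that fell, and 3 defence genes that rose. Leaving out bhlh93-1 0 h replicate 1 gave 5 floral integrators and 1 evening clock gene that rose, and 2 defence and 4 touch genes that fell. Leaving out replicate 3 gave 5 floral integrators that rose and 1 that fell. After cyclic loess 3 defence genes rose, and with dim genes dropped 0 light signalling genes did. Fitting array position left 2 flavonoid genes that rose and 1 touch and 1 evening clock gene that fell.

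limma called 7184 genes at 0 h. This count fell to 2998 without bhlh93-1 0 h replicate 2, to 3636 without Col-0 0 h replicate 2 and to 1812 without Col-0 0 h replicate 3; it was 1361 with array position as a covariate and 2765 when only the arrays of these groups were fitted. The groups did not overlap for 12330 genes (37.8%, where chance gives 10%), and of the 86 named genes called at 0 h, 19 kept their call under all alternatives tried, including LBD28, ELA2, ELF3, LHCB1.3, HEMA1, LNK2 and TPS8.

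At 4 h after the light came on, the comparison asks what the mutation changes in the day. The light-harvesting and chlorophyll synthesis lists lay lower and the GA inactivation list higher in bhlh93-1 at the preset correlation, and each lost its call with an estimated correlation (adjusted p = 0.793). LHCB1.3 fell 3.45-fold (log2 -1.79 ± 0.25, adjusted p = 0.00071) and LHCB1.2 fell 2.44-fold (log2 -1.29 ± 0.24). The clock gene LNK2 fell 2.29-fold (log2 -1.19 ± 0.23), and J20 (AT4G13830), a chloroplast DnaJ-type chaperone, rose 3.4-fold (log2 1.77 ± 0.25, and 1.77-fold when the models of a locus were averaged). In all, 8.6% of the loci were called: 990 genes were higher and 1810 lower in bhlh93-1, of which 397 and 1120 differed by 2-fold or more. The higher genes numbered 445, 143 and 279 and the lower ones 1094, 712 and 868 without Col-0 4 h replicates 1, 2 and 3. They were 203 and 832 without bhlh93-1 4 h replicate 2, and 508 and 1087 without bhlh93-1 4 h replicate 3. They were 266 and 689 with array position as a covariate. Annotated nuclear pseudogenes, 3858 of the 32627 loci, gave 94 of the 990 higher and 679 of the 1810 lower genes at 4 h. These were 61 and 750 after cyclic loess, and 456 and 308 at 0 h.

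The largest rises at 4 h were in GATA12 (3.66-fold, log2 1.87 ± 0.45, adjusted p = 0.0166, and 2.17-fold without bhlh93-1 4 h replicate 2), J20, USPL1 (3.39-fold), the cuticle regulator SHN3 (2.86-fold), LBD28 (2.83-fold), CYP702A7P, NIP4;1, GATA14, FLU (2.63-fold), which restrains chlorophyll synthesis in the dark, and hemb2. The largest falls were in the indole glucosinolate methyltransferase gene IGMT3 (4.28-fold, log2 -2.10 ± 0.34), XW6 (4.1-fold, adjusted p = 0.00034), the glutaredoxin gene GRXS13 (3.68-fold), RTFL17, LHCB1.3, the HSP90 genes Hsp81.4 (3.43-fold) and HSP81-3 (3.41-fold), the iron superoxide dismutase gene FSD1 (3.41-fold), ENODL19 and EDS5 (3.35-fold), which acts in salicylic acid accumulation. The calls of SHN3, LBD28 and GATA14 ended without Col-0 4 h replicate 2 (adjusted p = 0.0598, 0.0583 and 0.0596). Those of GATA12, SHN3, LBD28 and GATA14 ended without bhlh93-1 4 h replicate 2 (0.0599, 0.0623, 0.0612 and 0.0506). Those of GATA12 and GATA14 ended without Col-0 4 h replicate 3 (0.0685 and 0.0563), and that of GATA12 without Col-0 4 h replicate 1 (0.0578). CYP702A7P, NIP4;1, Hsp81.4, HSP81-3, FSD1 and EDS5 had adjusted p from 0.0512 to 0.142 with array position as a covariate, and FLU lost its call when the models of a locus were averaged (1.17-fold, adjusted p = 0.462). USPL1 rose 6.44-fold and RTFL17 fell 5.75-fold with array position as a covariate. With the models averaged FSD1 and GRXS13 fell 2.05-fold and 1.85-fold.

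Of 20 light-harvesting genes 7 fell at 4 h (13 adjusted over the list alone, camera adjusted p = 1.13e-05, and adjusted p = 0.793 with an estimated correlation). Of 15 chlorophyll synthesis genes 5 fell (9 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000271, and adjusted p = 0.793 with an estimated correlation), among them HEMA1 (2.3-fold, with an adjusted p of 0.0605 with array position as a covariate). Of 11 GA inactivation genes 2 rose (4 adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.793 with an estimated correlation): ELA2 by 1.04 ± 0.30 and the GA 2-oxidase gene GA2OX4 by 0.82 ± 0.23. The GA inactivation call also ended after cyclic loess (0.0506) and without Col-0 4 h replicate 1 (0.051), and with array position as a covariate it and the light-harvesting call ended (0.127 and 0.25). The count of light-harvesting genes that fell was 3 without any one of the Col-0 4 h replicates or bhlh93-1 4 h replicate 2 and 4 without bhlh93-1 4 h replicate 3. For chlorophyll synthesis it was 3, 1 and 2 without Col-0 4 h replicates 1, 2 and 3, and 3 and 2 without bhlh93-1 4 h replicates 2 and 3. Of the GA inactivation genes 1 rose without bhlh93-1 4 h replicate 1 and 0 without any other array at 4 h. The call of GA2OX4 was lost without any one of 5 arrays, with adjusted p of 0.113 without Col-0 4 h replicate 1, 0.0737 without Col-0 4 h replicate 2, 0.0929 without Col-0 4 h replicate 3, 0.148 without bhlh93-1 4 h replicate 2 and 0.0724 without bhlh93-1 4 h replicate 3. That of ELA2 was lost without any one of the 6 arrays at 4 h, with adjusted p from 0.075 to 0.154. With array position as a covariate they had 0.138 and 0.0542, and ELA2 rose by 1.71.

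The other 26 lists were not called at 4 h, with camera adjusted p from 0.201 to 0.974. In light signalling BBX25 and HY5, a promoter of light responses, rose by 1.02 ± 0.23 and 0.87 ± 0.24 and SPA1 fell by 0.92 ± 0.25 (2 rose and 1 fell of 16, the same adjusted over the list alone, camera adjusted p = 0.618). In the salicylic acid and defence list the pathogenesis-related gene PR1 and WRKY38 rose by 0.98 ± 0.28 and 0.93 ± 0.24, and EDS5 and the salicylate synthesis gene ICS1 fell by 1.74 ± 0.32 and 0.84 ± 0.25 (2 rose and 2 fell of 19, 3 and 2 adjusted over the list alone, camera adjusted p = 0.868). The nitrate reductase gene NIA2 fell by 1.12 ± 0.26, 1 of 12 nitrate assimilation genes (1 adjusted over the list alone, camera adjusted p = 0.938). The calls of BBX25 and NIA2 ended without Col-0 4 h replicate 2 (adjusted p = 0.0658 and 0.0611), Col-0 4 h replicate 3 (0.0633 and 0.0591) or bhlh93-1 4 h replicate 2 (0.0563 and 0.0677). Those of HY5, PR1 and ICS1 ended without any one of the 6 arrays at 4 h (0.0588 to 0.146, 0.0607 to 0.132 and 0.0675 to 0.179). Those of SPA1 and WRKY38 ended without any one of them but bhlh93-1 4 h replicate 1 (0.078 to 0.124 and 0.0592 to 0.0819). So the counts moved too. In light signalling 0 were called without Col-0 4 h replicate 2 or 3 or bhlh93-1 4 h replicate 2, 2 rose and 0 fell without Col-0 4 h replicate 1, 1 rose and 1 fell without bhlh93-1 4 h replicate 1, and 1 rose and 0 fell without bhlh93-1 4 h replicate 3 or with array position fitted. Of the defence genes 1 rose and 1 fell without bhlh93-1 4 h replicate 1 or with dim genes dropped, 0 rose and 1 fell without any other array at 4 h, 1 rose and 2 fell after cyclic loess, and 1 rose and 0 fell with array position fitted. Of the nitrate genes 1 rose and 1 fell without Col-0 4 h replicate 1. BBX25, WRKY38 and NIA2 stood at 1.57, 1.41 and -1.87 with array position as a covariate. None of the 20 floral integrators and promoters was called by limma, although 6 had an unadjusted p under 0.05 (camera adjusted p = 0.201); 1 fell after cyclic loess and 1 rose without bhlh93-1 4 h replicate 3.

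limma called 2800 genes at 4 h. The count fell to 1539, 855 and 1147 without Col-0 4 h replicate 1, 2 and 3, and to 1035 and 1595 without bhlh93-1 4 h replicate 2 and 3; it was 955 with array position as a covariate and 5314 when only the arrays of these groups were fitted. The groups did not overlap for 11858 genes (36.3%, where chance gives 10%), and 11 of the 42 named genes called at 4 h kept their call under all alternatives tried, including J20, LHCB1.3, LHCB1.2 and LNK2.

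Averaged over both times, the comparison sets 6 arrays against 6 and asks how the genotypes differ in the mean of night and day, so a difference at one time alone can pass. Of all loci 35.5% were called in it, so a single call or a count near that share is not particular to a gene or list. Among the genes that form the study's question, the photoperiod gene CO (AT5G15840) rose by 0.70 ± 0.19 (1.63-fold, adjusted p = 0.00944), the floral identity gene LFY (AT5G61850) by 0.71 ± 0.21 (1.64-fold, adjusted p = 0.0145), and the GA 2-oxidase gene GA2OX2 (AT1G30040) by 0.63 ± 0.16 (1.55-fold, adjusted p = 0.0062). The GA 20-oxidase genes GA20OX2 and GA20OX3, which act in GA synthesis, rose by 0.54 ± 0.14 and 1.12 ± 0.22. FT, SOC1 and FLC did not pass, with 0.25 ± 0.20, -0.67 ± 0.28 and -0.43 ± 0.20 (adjusted p = 0.323, 0.0646 and 0.107). GA20OX1, GA3OX1, GA2OX1 and GA2OX6 did not pass either, with adjusted p from 0.154 to 0.926. With array position as a covariate the adjusted p of CO, LFY and GA2OX2 were 0.173, 0.0836 and 0.089, with LFY at 1.26 and GA2OX2 at 0.95, and those of GA20OX2 and GA20OX3 were 0.376 and 0.0605. Over all alternatives the adjusted p of CO ran from 0.00146 to 0.173, that of LFY from 0.00415 to 0.0836 and that of GA2OX2 from 0.00349 to 0.089, with a rise of 0.37 and an adjusted p of 0.0564 when the locus's models were averaged.

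Of 20 floral integrators and promoters 7 rose in the averaged contrast (7 adjusted over the list alone, camera adjusted p = 0.0557), among them AP1 (log2 0.81 ± 0.21) and AGL24 (log2 0.79 ± 0.19). This count lies near the 35.5% called of all loci. Of 17 floral repressors 2 rose and 2 fell (2 rose adjusted over the list alone, camera adjusted p = 0.901): MAF5 rose 2.3-fold (1.59-fold when the models of a locus were averaged) and TOE3 by 0.78 ± 0.20 on the log2 scale, and SVP and TOE1 fell by 0.48 ± 0.17 and 0.46 ± 0.16. Of 11 GA inactivation genes 6 rose (6 adjusted over the list alone, camera adjusted p = 0.0123, and adjusted p = 0.628 with an estimated correlation), with ELA2 at 1.23 ± 0.21 and GA2OX3 at 1.04 ± 0.26. Of 14 GA biosynthesis genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.261). Of 16 GA signalling and response genes 3 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.64); the DELLA repressor genes RGL2 and RGL3 rose by 0.66 ± 0.18 and 0.60 ± 0.19, and GASA14 and GASA6 fell by 0.83 ± 0.19 and 0.85 ± 0.26. GASA6 turned to 0.21 with array position as a covariate, and its adjusted p was 0.0552 without Col-0 4 h replicate 1 and 0.0509 without bhlh93-1 4 h replicate 2. Of 12 autonomous and vernalization pathway genes 3 fell (3 adjusted over the list alone, camera adjusted p = 0.043, and adjusted p = 0.628 with an estimated correlation), with VRN5 at -0.74 ± 0.15. The call of this list ended without Col-0 0 h replicate 1 or 2 (0.0603 and 0.0516), Col-0 4 h replicate 1 (0.0637) or bhlh93-1 4 h replicate 1 or 2 (0.0505 and 0.051), and 5 of its genes fell without Col-0 4 h replicate 3. With dim genes dropped it had 0.186. Its median was -0.58 at 0 h and -0.09 at 4 h, where the list was not called (0.496). With array position as a covariate its adjusted p and that of GA inactivation were 0.306 and 0.123. Of these genes ELA2 kept its call with array position as a covariate (0.0175), and the others had 0.0506 to 0.816. The values with that covariate were 1.90 for ELA2, 0.40 for AGL24, -0.47 for GASA14, -0.17 for SVP and -0.23 for TOE1, and RGL2 rose 2.3-fold. The call of SVP ended without any one array (0.0545 to 0.109) except Col-0 4 h replicate 3, bhlh93-1 0 h replicate 2 and bhlh93-1 4 h replicates 1 and 3. That of TOE1 ended without any one array (0.0509 to 0.0794) except Col-0 0 h replicate 3, Col-0 4 h replicate 3, bhlh93-1 0 h replicates 1 and 3 and bhlh93-1 4 h replicate 1. That of RGL3 ended without Col-0 0 h replicate 3, Col-0 4 h replicate 3 or bhlh93-1 4 h replicate 3 (0.068, 0.0529 and 0.0614). After cyclic loess RGL2, RGL3 and TOE1 had 0.0526, 0.147 and 0.07, and TOE1 differed by -0.18 with the models of a locus averaged (0.283). The counts of the lists not called moved as well. Of the floral integrators 3 rose with dim genes dropped, and 1 fell without Col-0 4 h replicate 3 or bhlh93-1 0 h replicate 2 or 3. Of the floral repressors 0 fell without Col-0 0 h or 4 h replicate 1 or 2 or bhlh93-1 4 h replicate 2, and 1 without Col-0 0 h replicate 3, bhlh93-1 0 h replicate 1 or 2 or bhlh93-1 4 h replicate 3. Of the GA biosynthesis genes 0 fell without Col-0 0 h replicate 2 or 3, Col-0 4 h replicate 1, bhlh93-1 0 h replicate 2 or bhlh93-1 4 h replicate 1 or 2. Of the GA signalling genes 0 rose after cyclic loess or with dim genes dropped. There 2 rose and 2 fell without Col-0 0 h replicate 2 or bhlh93-1 4 h replicate 3, 1 rose and 2 fell without Col-0 0 h replicate 3, and 1 fell without Col-0 4 h replicate 1 or bhlh93-1 4 h replicate 2. Fitting array position left 0 genes called in these 4 lists.

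The photosynthesis and dark response lists were called in the averaged contrast at the preset correlation, and each lost its call with an estimated correlation. Of 15 chlorophyll synthesis genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), and of 20 light-harvesting genes 12 fell and 1 rose (12 and 1 adjusted over the list alone). Both lists had a camera adjusted p of 7.74e-05 and an adjusted p = 0.628 with an estimated correlation. LHCB1.3 fell by 1.81 ± 0.18 and HEMA1 by 1.28 ± 0.17, and LHCB4.3 and PORA rose by 0.47 ± 0.17 and 0.71 ± 0.19. Of 23 dark- or low-sugar-induced genes 10 fell (10 adjusted over the list alone, camera adjusted p = 0.00223, and adjusted p = 0.714 with an estimated correlation), with the branched-chain aminotransferase gene BCAT2 at -1.06 ± 0.23. At 0 h the median was -0.77. The list was not called at 4 h (camera adjusted p = 0.532), where none was called by limma, 7 had an unadjusted p under 0.05, and the median was -0.11, and 0.07 after cyclic loess. With array position as a covariate the light-harvesting and dark- or low-sugar-induced calls ended (0.306 and 0.207), and after cyclic loess the adjusted p of all 5 lists called in this contrast ran from 0.11 to 0.434. The dark- or low-sugar-induced genes that fell numbered 6 without Col-0 0 h replicate 2, Col-0 4 h replicate 1 or bhlh93-1 4 h replicate 2. The largest averaged rises were in LBD28 (3.4-fold), CYP702A7P (3.02-fold), GATA14 (3.01-fold), USPL1 (2.82-fold), SHN3, NIP4;1, bZIP42, RSL1, RALFL29 and AGP6, and the largest falls in U1.5 (4.51-fold), GRXS13 (3.73-fold, and 1.63-fold with the models of a locus averaged), LHCB1.3 (3.49-fold), KCS16, XW6, ECT3, RNS2, XTH24, FKBP13 and RTFL17. limma called 11590 genes, 6150 higher and 5440 lower, and 1936 with array position as a covariate (853 and 1083). More genes were lower than higher with that covariate, after cyclic loess (4931 higher and 5439 lower) and with dim genes dropped (4200 and 5139). Of all named genes called here, 28 of 110 kept their call under all alternatives tried. The falls of U1.5, XTH24, ECT3 and RTFL17 were 11.1-fold, 7.75-fold, 7.23-fold and 4.85-fold with array position as a covariate, and the rises of USPL1 and bZIP42 5.35-fold and 4.53-fold. With it PORA, LHCB4.3, BCAT2, CYP702A7P, SHN3, RNS2 and FKBP13 had adjusted p from 0.0584 to 0.203, and PORA had 0.0531 with the models of a locus averaged. LHCB4.3 stood at 0.96 with the covariate, and its call also ended without Col-0 0 h replicate 3 (0.113), Col-0 4 h replicate 2 or 3 (0.0725 and 0.0962), bhlh93-1 0 h replicate 1 (0.0941) or bhlh93-1 4 h replicate 1 or 3 (0.0986 and 0.0968).

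**Figure D1:**
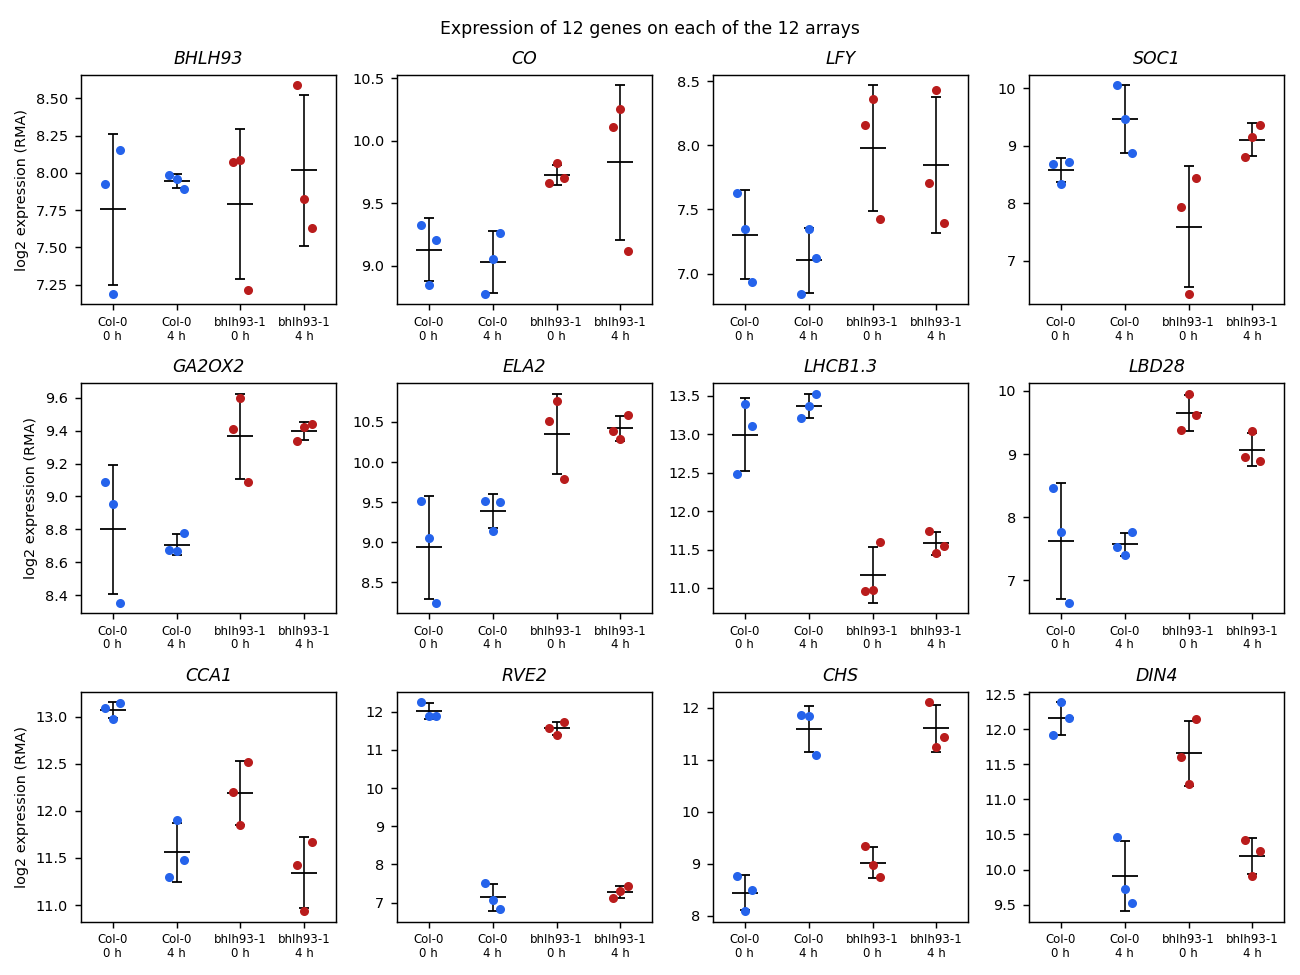
Expression of 12 genes on each array, in log2 RMA units on the vertical axis, by genotype and time on the horizontal axis; points are arrays, horizontal dashes are group means and bars are ± 1 SD (n = 3). LHCB1.3 lay lower and LBD28 higher on every bhlh93-1 array than on any Col-0 array, while RVE2 and CHS separated the times in both genotypes.

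The change from 0 h to 4 h in Col-0 sets wild-type seedlings harvested 4 h after the light came on against those harvested in the dark. No sample was kept dark until 4 h, so the change holds any effect of light together with that of the time of day. The morning clock and dark- or low-sugar-induced lists lay lower and the flavonoid and light-harvesting lists higher at the preset correlation. With an estimated correlation the flavonoid call held (adjusted p = 0.00681) and the others were lost (0.184 to 0.228). The MYB gene RVE2 (AT5G37260) fell 29.3-fold (log2 -4.87 ± 0.22, adjusted p = 1.02e-09), the clock gene LHY (AT1G01060) 7.33-fold (log2 -2.87 ± 0.25) and its partner CCA1 (AT2G46830) 2.85-fold (log2 -1.51 ± 0.24). CHS (AT5G13930), the first enzyme of flavonoid synthesis, rose 8.83-fold (log2 3.14 ± 0.28), and AOC2 (AT3G25770), an allene oxide cyclase of jasmonate synthesis, rose 12-fold (log2 3.58 ± 0.21). In all, 1015 genes rose and 1462 fell, of which 573 and 855 changed by 2-fold or more. More genes rose than fell without Col-0 0 h replicate 3 (1126 and 1027) or Col-0 4 h replicate 3 (623 and 609).

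The other large rises in Col-0 were in the plastid fibrillin gene FIB (13.6-fold), the methionine synthase gene MS2 (11.2-fold), KAT5 (9.78-fold), the S-adenosylhomocysteine hydrolase gene SAHH2 (9.43-fold), GH9C2 (9.37-fold), scpl10, XTH32 and the cytosolic fumarase gene FUM2 (7.44-fold). The other large falls were in COR27 (11.1-fold), CDF2 (7.01-fold), a repressor of CO, XTH25 (6.75-fold), COL9 (6.06-fold), OXS3, PYL5, AAE5 and TBL37. Each of these genes kept its call under all alternatives tried. The fall of OXS3 went from 5.82-fold to 9.44-fold without Col-0 4 h replicate 1, and that of CDF2 was 3.53-fold with the models of a locus averaged.

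Of 23 dark- or low-sugar-induced genes 11 fell in Col-0 (18 adjusted over the list alone, camera adjusted p = 3.41e-15, and adjusted p = 0.228 with an estimated correlation), with DIN4 at -2.26 ± 0.28 and IVD, both of branched-chain amino acid breakdown, at -1.97 ± 0.24. Of 18 phenylpropanoid and flavonoid genes 8 rose (10 adjusted over the list alone, camera adjusted p = 2.08e-09), with PAL1 at 2.21 ± 0.37. This list alone among all called lists kept its call with an estimated correlation (adjusted p = 0.00681). Of 20 morning clock genes 9 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 1.39e-07, and adjusted p = 0.184 with an estimated correlation); PRR9 rose by 1.99 ± 0.24. Of 20 light-harvesting genes 6 rose (10 adjusted over the list alone, camera adjusted p = 3.73e-07, and adjusted p = 0.228 with an estimated correlation), with LHCB3 at 1.25 ± 0.24. Of 15 chlorophyll synthesis genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.00979, and adjusted p = 0.364 with an estimated correlation), with PORB and PORC at 1.72 ± 0.26 and 1.54 ± 0.20. Each of these 5 lists kept its call at the preset correlation without any one array, while some counts moved. The dark- or low-sugar-induced genes that fell numbered 5 without Col-0 0 h replicate 2 or Col-0 4 h replicate 2 or 3. Only 1 morning clock gene rose without Col-0 0 h replicate 1 or 3 or Col-0 4 h replicate 2, and 2, 3 and 2 light-harvesting genes rose without Col-0 0 h replicate 1, Col-0 4 h replicate 1 and Col-0 4 h replicate 2.

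Stress and hormone lists were called between the times as well, none with an estimated correlation. Of 14 cold and ABA genes 5 rose (6 adjusted over the list alone, camera adjusted p = 4.99e-05, and adjusted p = 0.228 with an estimated correlation), with RD29A at 1.72 ± 0.26 and ERD10 at 1.57 ± 0.24. Of 12 heat shock genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.00979, and adjusted p = 0.182 with an estimated correlation): HSP70 by 1.98 ± 0.22 and HSP90.1 by 1.32 ± 0.24. Of 22 jasmonate genes 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.231 with an estimated correlation), with LOX2 at 2.53 ± 0.32 and JAZ3 at -1.05 ± 0.28. Of 17 floral repressors 4 fell (5 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.231 with an estimated correlation), with TEM1 and TEM2, repressors of FT, at -2.24 ± 0.27 and -1.41 ± 0.26. Of 9 touch and wounding genes TCH4 fell by 1.32 ± 0.33 (3 fell adjusted over the list alone, camera adjusted p = 0.0315, and adjusted p = 0.565 with an estimated correlation). Of 16 GA signalling and response genes 2 fell (3 adjusted over the list alone, camera adjusted p = 0.0424, adjusted p = 0.413 with an estimated correlation, and 0.0506 after cyclic loess): SCL3 by 0.93 ± 0.25 and SPY, which restrains GA responses, by 0.88 ± 0.19. With dim genes dropped the floral repressor, touch and wounding and GA signalling calls ended (0.0524, 0.0744 and 0.0795), and the last also with a replicate block (0.0563). The floral repressor call ended without Col-0 4 h replicate 3 (0.0552), and 2 of its genes fell without that array or Col-0 0 h replicate 1. The touch and wounding call ended without Col-0 0 h replicate 2 or 3 or Col-0 4 h replicate 1 or 3 (0.0782, 0.11, 0.0912 and 0.0884). The GA signalling call ended without Col-0 0 h replicate 1 or 2 or Col-0 4 h replicate 3 (0.0812, 0.0782 and 0.233) and with array position as a covariate (0.103). The call of JAZ3 ended without Col-0 0 h replicate 1 or 2 or Col-0 4 h replicate 2 or 3 (0.0779, 0.0882, 0.106 and 0.171). That of TCH4 ended without Col-0 0 h replicate 2 or 3 or Col-0 4 h replicate 2 or 3 (0.0635, 0.0781, 0.0704 and 0.116). That of SCL3 ended without any one Col-0 array except 0 h replicate 3 (0.0616 to 0.137), and that of SPY without Col-0 4 h replicate 3 (0.0504) and with the models of a locus averaged (log2 -0.49, adjusted p = 0.136).

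The other 18 lists were not called in Col-0, with camera adjusted p from 0.102 to 0.917. In light signalling BBX22 and ELIP1 rose by 1.90 ± 0.21 and 1.65 ± 0.25, and RUP1 and BBX25 fell by 1.99 ± 0.26 and 1.66 ± 0.23 (3 rose and 6 fell of 16, the same adjusted over the list alone, camera adjusted p = 0.102, and 3 fell without Col-0 0 h replicate 1 or Col-0 4 h replicate 3). PIF4, a growth-promoting phytochrome-interacting factor, rose by 2.32 ± 0.27, GI by 2.48 ± 0.22 and the nitrite reductase gene NIR1 by 1.09 ± 0.22. FT, LFY, CO, FLC and the GA oxidase genes always named were not called, and the adjusted p of SOC1 was 0.203. limma called 2477 genes, and 1277 without Col-0 0 h replicate 1, 1131 without Col-0 4 h replicate 2 and 1232 without Col-0 4 h replicate 3. The groups did not overlap for 9305 genes (28.5%, where chance gives 10%), and 43 of the 60 named genes called kept their call under all alternatives tried.

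In bhlh93-1 the change from 0 h to 4 h sets the same times against each other in the mutant. The light-harvesting, chlorophyll synthesis and flavonoid lists lay higher and the dark- or low-sugar-induced list lower at the preset correlation, and each lost its call with an estimated correlation (adjusted p = 0.203 to 0.735). The morning clock and jasmonate lists were not called (camera adjusted p = 0.365 for each), while single members changed. RVE2 fell 19.4-fold (log2 -4.28 ± 0.22, adjusted p = 9.44e-09) and LHY 3.46-fold (log2 -1.79 ± 0.25), and CHS rose 5.97-fold (log2 2.58 ± 0.28) and AOC2 7.13-fold (log2 2.84 ± 0.21). CCA1 differed by -0.84 ± 0.24 and did not pass (adjusted p = 0.0539, and 0.0169 after cyclic loess). In all, 954 genes rose and 665 fell, of which 554 and 357 changed by 2-fold or more. More fell than rose without bhlh93-1 0 h replicate 2 (659 rose and 693 fell). The flowering gene SOC1 (AT2G45660) rose by 1.51 ± 0.39 (2.85-fold, adjusted p = 0.0319). Without bhlh93-1 0 h replicate 2 its rise was 0.93 (adjusted p = 0.0946). Its adjusted p was 0.062 without bhlh93-1 4 h replicate 1, 0.0805 without bhlh93-1 4 h replicate 2 and 0.125 without bhlh93-1 4 h replicate 3. It was 0.102 when only the arrays of this contrast were fitted. In Col-0 SOC1 differed by 0.89 ± 0.39 (adjusted p = 0.203), and its interaction had an adjusted p of 0.805.

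The other large rises in bhlh93-1 were in FIB (9.94-fold), MS2 (8.42-fold), SAHH2 (7.07-fold), Hsp89.1 (6.76-fold), KAT5 (6.04-fold), Cpn60beta2, a subunit of the chloroplast chaperonin (5.62-fold), RD22 and FUM2. The other large falls were in CDF2 (4.91-fold), COL9 (4.09-fold), COL2 (4.07-fold), KUF1, RALF23, COR27, EXO70B2 and MIM. Of 20 light-harvesting genes 2 rose (8 adjusted over the list alone, camera adjusted p = 1.53e-05, and adjusted p = 0.366 with an estimated correlation), with LHCB1.5 at 1.08 ± 0.27. Of 15 chlorophyll synthesis genes 3 rose (5 adjusted over the list alone, camera adjusted p = 0.000148, and adjusted p = 0.366 with an estimated correlation), with PORB at 1.75 ± 0.26 and the chloroplast development regulator GLK1 at 1.19 ± 0.21. Of 23 dark- or low-sugar-induced genes 3 fell (5 adjusted over the list alone, camera adjusted p = 0.00152, and adjusted p = 0.735 with an estimated correlation), with the glutamate dehydrogenase gene GDH1 at -1.55 ± 0.31 and DIN4 at -1.47 ± 0.28. Of 18 phenylpropanoid and flavonoid genes 5 rose (8 adjusted over the list alone, camera adjusted p = 0.00177, and adjusted p = 0.203 with an estimated correlation). Of 20 morning clock genes 5 fell and 1 rose (8 and 4 adjusted over the list alone, camera adjusted p = 0.365); the median of this list was 0.15 and its mean -0.33. Of 22 jasmonate genes 3 rose (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.365), with a median of -0.04 and a mean of 0.19. Of the morning clock genes 7 fell and 3 rose after cyclic loess or with dim genes dropped, 4 fell and 3 rose without bhlh93-1 0 h replicate 3, and 3 fell without bhlh93-1 4 h replicate 1 or 2. Of the jasmonate genes 1 fell without bhlh93-1 0 h replicate 1, with dim genes dropped, with a replicate block or with array position fitted. The call of LHCB1.5 ended without bhlh93-1 0 h replicate 2 or 3 (adjusted p = 0.0612 and 0.0656) or bhlh93-1 4 h replicate 1 or 3 (0.12 and 0.0507). COR27 had 0.0635 when only the arrays of this contrast were fitted, and its fall went from 3.56-fold to 5.63-fold without bhlh93-1 0 h replicate 2. That of CDF2 was 2.56-fold with the models of a locus averaged. The dark- or low-sugar-induced call ended without bhlh93-1 0 h replicate 3 (0.188) or bhlh93-1 4 h replicate 2 (0.0933), and 5 of its genes fell without bhlh93-1 0 h replicate 2. Of the light-harvesting genes 0 rose without bhlh93-1 0 h replicate 2 or 3 or bhlh93-1 4 h replicate 1 or 3, and 1 without bhlh93-1 4 h replicate 2.

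The remaining lists were not called in bhlh93-1 either, with camera adjusted p from 0.117 to 0.974. MAF5 and TEM1 fell by 1.57 ± 0.30 and 1.18 ± 0.27 (2 rose and 3 fell of 17 floral repressors, 3 and 6 adjusted over the list alone, camera adjusted p = 0.155). FVE, of the autonomous pathway, rose by 1.24 ± 0.28, and the GA synthesis gene KAO1 fell by 1.23 ± 0.22. HSP70 rose by 1.89 ± 0.22 and HSP90.1 by 1.02 ± 0.24, 2 of 12 heat shock genes (2 adjusted over the list alone, camera adjusted p = 0.117). The calls of TEM1, FVE and HSP90.1 ended without bhlh93-1 4 h replicate 1 (adjusted p = 0.0773, 0.0724 and 0.062) or bhlh93-1 4 h replicate 3 (0.0701, 0.0947 and 0.111). Those of TEM1 and HSP90.1 ended without bhlh93-1 0 h replicate 3 (0.0569 and 0.0528) and that of FVE without bhlh93-1 0 h replicate 2 (0.0586). MAF5 differed by -0.72 when the models of a locus were averaged (0.111). Of the floral repressors 0 rose without bhlh93-1 0 h replicate 1 or 2 or with a replicate block, and 1 without bhlh93-1 4 h replicate 2, after cyclic loess or with array position fitted. Only 1 fell without bhlh93-1 0 h replicate 3 (1 rose) or bhlh93-1 4 h replicate 1 or 3 (0 rose). Of the heat shock genes 1 rose without bhlh93-1 0 h or 4 h replicate 3. limma called 1619 genes, 711 without bhlh93-1 4 h replicate 1, 712 without bhlh93-1 4 h replicate 3 and 456 when only the arrays of this contrast were fitted. The groups did not overlap for 6971 genes (21.4%, where chance gives 10%), and 35 of the 52 named genes called kept their call under all alternatives tried.

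**Figure D2:**
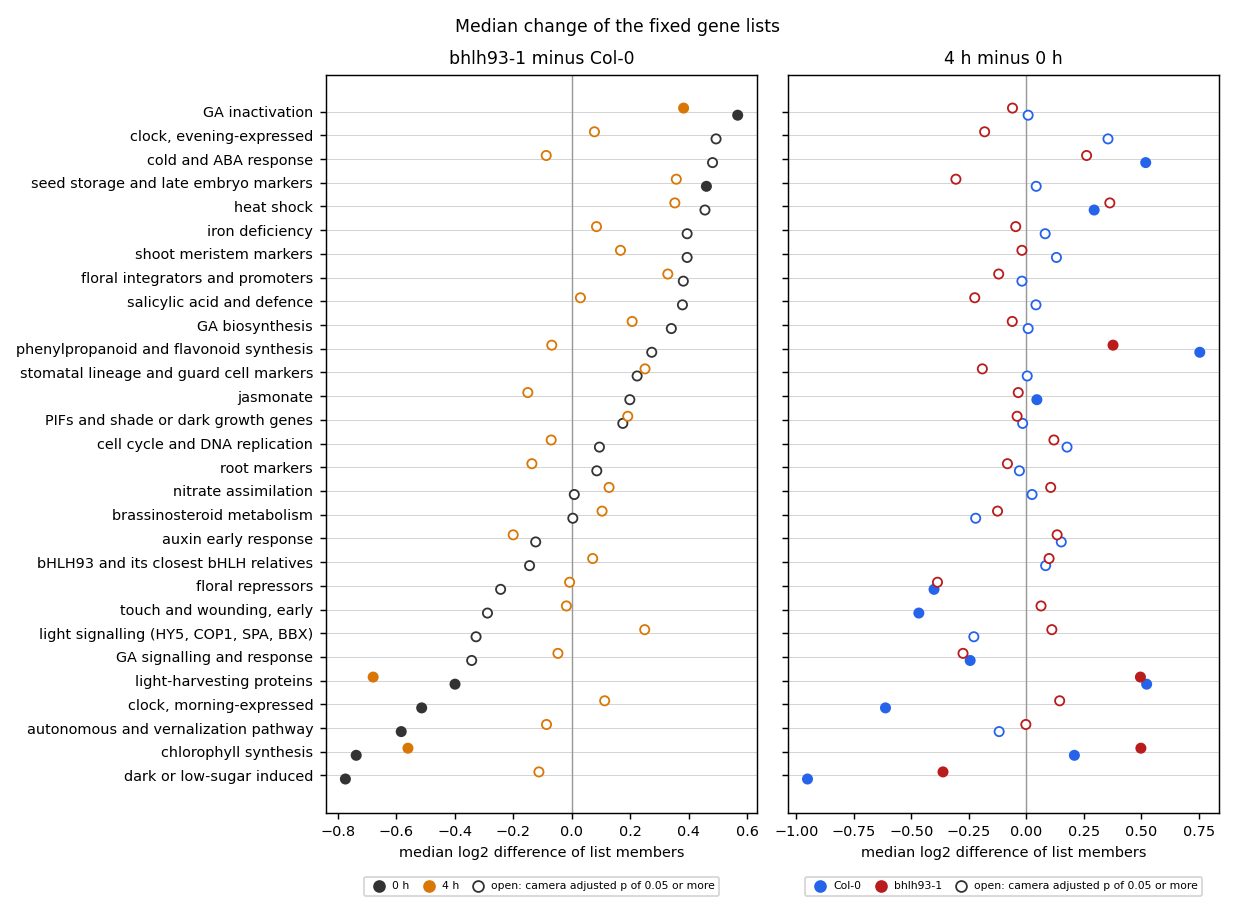
Median log2 difference of the members of each of the 29 fixed lists, bhlh93-1 minus Col-0 on the left and 4 h minus 0 h on the right; filled points passed the camera test at the preset correlation and open points did not. The medians of the chlorophyll synthesis and light-harvesting lists lay below 0 in bhlh93-1 at both times, and that of the dark- or low-sugar-induced list lay below 0 from 0 h to 4 h in both genotypes; of all filled points only flavonoid synthesis in Col-0 kept its call with an estimated correlation.

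The interaction asks whether the change from 0 h to 4 h differs between the genotypes. limma called 0 genes, with 2344 at an unadjusted p under 0.05 and a smallest adjusted p of 0.12, so for no single gene was the change with time shown to differ. The smallest p-values belonged to AT2G46670 (log2 -2.33 ± 0.35), TPPE, a trehalose phosphate phosphatase gene (log2 -1.76 ± 0.32, adjusted p = 0.473), AT1G41770, EXPA23 and scpl10, given as values that did not pass. Leaving out Col-0 0 h replicate 3 or bhlh93-1 0 h replicate 1 gave 1 called gene each.

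At the level of lists, 7 differed in the interaction at the preset correlation, and none kept its call with an estimated correlation. The dark- or low-sugar-induced list had a median interaction of 0.55 (camera adjusted p = 2.43e-07, and adjusted p = 0.438 with an estimated correlation), so its median fall was smaller in bhlh93-1. This median was 0.36 without bhlh93-1 0 h replicate 2, and 0.86, 0.85 and 0.82 without Col-0 0 h replicate 1, Col-0 4 h replicate 1 and bhlh93-1 0 h replicate 3. None of the 23 was called by limma, 6 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone. IVD had an interaction of 1.31 ± 0.34 (adjusted p = 0.639). The morning clock list had a median of 0.51 (camera adjusted p = 2.92e-07, and adjusted p = 0.289 with an estimated correlation). None of its 20 members was called by limma, 6 had an unadjusted p under 0.05, and 4 passed adjusted over the list alone; LHY had 1.08 ± 0.35 and RVE4 1.69 ± 0.46. The flavonoid list had a median of -0.53 (camera adjusted p = 0.00224, and adjusted p = 0.221 with an estimated correlation), with 4 of 18 members at an unadjusted p under 0.05 and none called by limma.

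Genotype differences at 0 h and at 4 h resembled each other across genes, with Pearson r = 0.706 and Spearman rho = 0.697 over 32627 genes, which are not independent replicates. Of the called genes 590 were higher and 984 lower at both times, where 113.8 and 190.4 would be shared by chance, and 3 went opposite ways. Both times Col-0 held the lower array positions, so this sharing cannot be laid to the genotype alone. The changes from 0 h to 4 h in Col-0 and bhlh93-1 had r = 0.555 and rho = 0.436; 494 genes rose and 398 fell in both, where 29.7 and 29.8 would be shared by chance, and 0 went opposite ways.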

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

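Of the tests in this part, both tests of the smaller change with time in bhlh93-1 and the lists without single arrays were chosen only after the result was seen; the interaction of the gene lists and the count of other splits were planned.

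The change from 0 h to 4 h differed between bhlh93-1 and Col-0 for 7 gene lists in the test of the interaction itself, with camera at the preset correlation. The lists that lay higher in bhlh93-1 than their change in Col-0 were the dark- or low-sugar-induced genes (median 0.55, adjusted p = 2.43e-07, and adjusted p = 0.438 with an estimated correlation), the morning clock genes (0.51, 2.92e-07 and 0.289) and the light signalling genes (0.41, 0.000528 and 0.438). Touch and wounding genes (0.54, 0.0341 and 0.688) and autonomous and vernalization pathway genes (0.33, 0.0372 and 0.438) lay higher as well, and both lost the call after cyclic loess (adjusted p = 0.0873 and 0.127) and with dim genes dropped (0.0776 and 0.164). The touch and wounding call also ended without any one of 6 arrays (0.0765 to 0.538): Col-0 0 h replicates 2 and 3, Col-0 4 h replicates 1 and 3, bhlh93-1 0 h replicate 2 and bhlh93-1 4 h replicate 2. Its median was 0.17 without either of the last 2 arrays. The autonomous pathway call ended without any one of 7 arrays (0.053 to 0.145): Col-0 0 h replicates 2 and 3, Col-0 4 h replicate 3, bhlh93-1 0 h replicates 1 and 2, and bhlh93-1 4 h replicates 1 and 3. Its median was 0.19 without Col-0 4 h replicate 3 and 0.21 without bhlh93-1 0 h replicate 2. Lists that lay lower were the phenylpropanoid and flavonoid genes (-0.53, 0.00224 and 0.221) and the cold and ABA genes (-0.27, 0.00929 and 0.438). For each list the values in brackets are the median interaction, the adjusted p at the preset correlation and the adjusted p with an estimated correlation, and no list kept its call with the latter. The cold and ABA call ended without Col-0 4 h replicate 2 (0.0877) or bhlh93-1 0 h replicate 2 (0.0578). Its median was -0.18 without the latter, and -0.46 and -0.43 without bhlh93-1 0 h replicate 1 and bhlh93-1 4 h replicate 1. The dark- or low-sugar-induced list, whose median moved as given above, kept its call at the preset correlation without any one array. So did the morning clock, light signalling and flavonoid lists. Among single genes limma called 0 in the interaction.

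In bhlh93-1 the median change of the morning clock, light signalling and touch lists turned sign, and that of the other lists above was smaller. Across genes, which are not independent replicates, the noise-corrected slope of the bhlh93-1 change on the Col-0 change was 0.783 (jackknife SE over arrays 0.302). Neither explanation tested could be excluded. The narrower log2 range of the bhlh93-1 arrays predicts a slope near 0.916, the ratio of the array SDs, which lies within 1 SE of the slope, and leaving out bhlh93-1 0 h replicate 2 gave 0.81 (SE 0.224). Leaving out 1 array at a time gave 0.662 to 1.03, the last without Col-0 4 h replicate 3, so a slope of 1 is not excluded either. An effect of the mutation on the response to light or to the time of day, which the samples do not separate, stays open as untested.

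Other splits of the arrays tell little about the interaction. All 100 splits drawn gave at least as many calls as the real split, which gave 0, and the highest gave 11590. That split exchanges the genotype names at 4 h, so it turns the interaction into the averaged genotype difference, a structure of the samples.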

How the results depend on the processing

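With the position covariate limma called 1361 genes between genotypes at 0 h, 955 at 4 h and 1936 averaged. The differences did not shrink in the median, though those of single genes moved both ways. The median log2 size of the main calls went from 0.94 to 1.1 at 0 h, from 1.02 to 1.3 at 4 h and from 0.68 to 0.83 averaged, while the median standard error grew from 0.244 to 0.398 at either time and from 0.173 to 0.359 averaged. When only the arrays of a contrast were fitted, counts fell to 2765 at 0 h and 456 for 4 h minus 0 h in bhlh93-1. They rose to 5314 at 4 h and 3368 for 4 h minus 0 h in Col-0. Both that fell hold the bhlh93-1 0 h arrays. Leaving out 1 array at a time gave 1812 to 9294 genes at 0 h, 855 to 2091 at 4 h, 1131 to 2153 for 4 h minus 0 h in Col-0, 711 to 1728 for 4 h minus 0 h in bhlh93-1 and 0 to 1 for the interaction, with fewer arrays in each fit. The averaged genotype count stayed within 1.5 times the main count without any one array (8772 to 12859). Cyclic loess, dropping dim genes, the trended and robust variance, the replicate block and the mean of a locus's models left every count within 1.5 times, and the series table's values moved nothing. Between the genotype differences at 0 h and 4 h the correlation across genes was 0.834 with the position covariate and 0.641 to 0.745 without 1 array; between the changes from 0 h to 4 h it was 0.611 with dim genes dropped and 0.432 to 0.652 without 1 array. The cause of these shifts was not tested. Of 350 calls of named genes 136 were kept under every alternative and 265 under all but leaving out an array and the position covariate. Averaged, GASA6 turned to 0.213 (adjusted p = 0.816) with the position covariate, and AT5G65660 to 0.406 (0.0304) after cyclic loess, of untested cause. Of 37 called lists 1 kept its call with an estimated correlation, 21 after cyclic loess, 26 with the position covariate, 30 with dim genes dropped, 36 with the replicate block and 26 without any one array. Without background values per gene, signal over background cannot be given.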

Other observations

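Tests of the brightness trend, of array position and of the organelle-encoded genes in this part were chosen only after the results were seen; the count of other splits and the check of separate processing were planned.

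Genes encoded in the chloroplast genome, which the fixed lists do not cover, were lower in bhlh93-1. Of 87 such genes 69 fell at 0 h and 57 at 4 h, with median log2 differences of -1.02 and -0.94 (n = 3 arrays per group), and 40 fell at each time after cyclic loess, with medians of -0.58 and -0.71. Of 107 genes encoded in the mitochondrial genome 33 fell and 3 rose at 0 h, and 14 fell and 2 rose at 4 h, with medians of -0.45 and -0.26 (-0.20 and -0.13 after cyclic loess).

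Among lists the report has not described, none was called by camera between the genotypes averaged over both times, where limma called 35.5% of all loci. Of 22 shade and dark growth genes 5 rose and 1 fell (5 rose adjusted over the list alone, camera adjusted p = 0.616), with the shade-induced homeobox gene ATHB2 at 0.90 ± 0.23 (SE, n = 6 per genotype) and PAR2 at 0.63 ± 0.18. Of 17 early auxin response genes 1 rose and 5 fell (2 and 6 adjusted over the list alone, 0.296), with IAA7 at -1.02 ± 0.19. Of 10 shoot meristem markers 3 rose (3 adjusted over the list alone, 0.452), with the floral regulator UFO at 0.95 ± 0.20, and of 22 cell cycle genes 1 rose and 2 fell (1 and 1 adjusted over the list alone, 0.977), with the mitotic cyclin gene CYCB1;4 at 0.74 ± 0.18. Of 12 iron deficiency genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, 0.327), with MYB10 at 0.75 ± 0.18. Of 14 root markers 2 rose and 4 fell (2 and 5 adjusted over the list alone, 0.782), and of 10 stomatal markers 3 rose and 2 fell (4 and 2 adjusted over the list alone, 0.71), with SPCH, which starts the stomatal lineage, at 0.75 ± 0.20. Of 8 brassinosteroid genes 1 fell (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0.901), and of bHLH93 and its 3 closest relatives limma called 0, with 1 at an unadjusted p under 0.05 (0.985). ATHB2, PAR2, UFO and CYCB1;4 kept their calls under all alternatives tried. With array position as a covariate they stood at 2.11, 1.39, 1.57 and 1.31, while IAA7, MYB10 and SPCH had adjusted p of 0.0865, 0.176 and 0.125. IAA7 differed by -0.38 (0.049) with the models of a locus averaged. The counts of these lists moved with the setting. With bhlh93-1 0 h replicate 2 left out 2 iron deficiency and 3 cell cycle genes rose, and after cyclic loess 1 iron deficiency gene rose and 0 fell, and 3 cell cycle genes rose and 5 fell. The iron deficiency genes that rose were also 2 without Col-0 0 h replicate 2, Col-0 4 h replicate 1 or 3 or bhlh93-1 4 h replicate 1, and with dim genes dropped. For cell cycle 1 fell without Col-0 0 h replicate 2 or 3, Col-0 4 h replicate 1 or 2 or bhlh93-1 4 h replicate 2, 2 rose and 1 fell without bhlh93-1 0 h or 4 h replicate 3, and 2 rose without bhlh93-1 4 h replicate 1. Of the shade and dark growth genes 3 rose without Col-0 4 h replicate 3, bhlh93-1 0 h replicate 1 or bhlh93-1 4 h replicate 1, and 0 fell without any one array except Col-0 0 h replicate 1, Col-0 4 h replicate 2 and bhlh93-1 0 h replicates 1 and 3. Of the auxin genes 3 fell without Col-0 0 h replicate 3 (0 rose) or Col-0 4 h replicate 1, 2 rose without bhlh93-1 4 h replicate 2, and 0 rose without bhlh93-1 4 h replicate 1 or after cyclic loess. Of the shoot meristem markers 4 rose and 1 fell without bhlh93-1 4 h replicate 1. Of the root markers 1 rose without Col-0 0 h replicate 1 or 3, Col-0 4 h replicate 2, bhlh93-1 0 h replicate 1 or bhlh93-1 4 h replicate 1 or 3, 4 rose without bhlh93-1 0 h replicate 3, and 2 fell without bhlh93-1 4 h replicate 2 or 3 or after cyclic loess. Of the stomatal markers 1 fell with dim genes dropped or without any one array except bhlh93-1 0 h replicate 3 and bhlh93-1 4 h replicates 1 and 3. Of the brassinosteroid genes 2 rose without bhlh93-1 0 h replicate 1 (1 fell) or after cyclic loess (0 fell), 1 rose without Col-0 0 h replicate 1 or Col-0 4 h replicate 1 or with dim genes dropped, and 0 fell without Col-0 0 h or 4 h replicate 2 or bhlh93-1 4 h replicate 3. Of bHLH93 and its relatives 1 rose without Col-0 4 h replicate 3. Fitting array position left 3 shade and dark growth genes and 1 shoot meristem, 1 cell cycle, 1 iron deficiency and 1 root gene called, all as rises.

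limma called 7184 genes between the genotypes at 0 h and 2800 at 4 h. The narrower log2 range of the bhlh93-1 arrays, as far as it follows brightness, is argued against as the whole cause. After cyclic loess, which removes the trend with brightness, 65.1% of the calls at 0 h and 86% at 4 h stayed in the same direction. Differences between the arrays that do not follow brightness would survive cyclic loess, so they stay open. A linear trend along the array positions stays open, for the calls as a whole or in single genes. Fitting it did not take the differences towards 0, but called genes were picked for small within-group spread, which a trend widens. The median log2 difference of the called genes, in the direction of the call, went from 0.939 to 1.1 at 0 h (array jackknife SE 0.34) and from 1.021 to 1.298 at 4 h (SE 0.297). Across genes the trend's slope within groups correlated with the genotype difference at r = -0.35, where the trend as the cause needs a positive r. By group r was -0.623 and -0.195 at 0 h and 0.136 and 0.051 at 4 h (Col-0 first). Most calls ended all the same, 1183 and 801 staying in the same direction, with larger SEs. Processing of the bhlh93-1 arrays apart from the Col-0 arrays cannot be told apart from the genotype, since 0 bhlh93-1 arrays lie among positions 1 to 6. The genotype itself and carried-over genomic DNA stay open as well, as untested here.

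Averaged over both times, 1 of 100 splits of the arrays, the real one, gave 11590 genes and the highest other 3484. Chance is unlikely there if the arrays are independent, which the labels do not say. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts were 7184 at 0 h, 2800 at 4 h, and 2477 and 1619 for 4 h minus 0 h in Col-0 and bhlh93-1. The highest other was 0 in each.

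The lower organelle-encoded genes were weighed relative to protein-coding genes of like brightness, in exact permutation tests of array means over 400 regroupings within times. The narrower range of the bhlh93-1 arrays is argued against, since after cyclic loess chloroplast genes still lay lower, by -0.832 at 0 h and -0.857 at 4 h (within-group SD 0.211, exact p = 0.005, two-sided, the smallest these regroupings can give). Genomic DNA carried over into the Col-0 labelling may play a part and stays open: nuclear pseudogenes differed by -0.048 at 0 h and -0.268 at 4 h (SD 0.081, exact p = 0.035), the first within the spread. Whether chloroplast transcripts alone are lower stays open too, with mitochondrial genes at -0.232 and -0.154 (SD 0.201, exact p = 0.14). An effect of the mutation on chloroplast transcripts stays open as untested, as does the oligo-dT priming of the cDNA.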
